A study of Homo sapiens with 6 samples.

How the data were processed

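RNA from SK-Hep1 cells was measured on 6 single-colour arrays, 1 per sample, 3 from mock-treated cells and 3 from cells transfected with anti-miR-21. Per the labels' protocols, cells were plated 24 hours before a lipid transfection in which anti-miR-21 was present at 20 nM or absent, and were collected 16 hours later. RNA was amplified to biotin-labelled cRNA. The protocol for collection cites an Argonaute immunoprecipitation procedure, whereas the design text and the molecule label give total RNA. The sources used here do not settle which fraction was hybridised, and the samples are described below as total RNA, as labelled.

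The authors deposited log2 expression values for 54675 probe sets, made with GCRMA per the submitters' processing notes. GCRMA corrects background with probe sequence, normalizes between arrays and summarises each probe set on a log2 scale. Its version and settings are not given in the sources used here. The values ran from 0.0443 to 16.2, with array medians between 3.03 and 3.16 and no centring by gene. No scanner file was used here, so background correction and summarisation could not be varied. GCRMA pulls dim probe sets towards a common low level, so folds that start near that level are less certain than folds between bright values.

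Probe sets were named from the platform annotation supplied with the series, with symbols updated through Entrez identifiers against a RefSeq gene table of GRCh38.p14. Of 54613 probe sets other than the 62 controls, 41091 listed 1 gene, 1801 listed several and 11721 were unnamed in the annotation used here. Among annotation entries with 1 gene, 41043 matched the RefSeq table by identifier, 54 did not and kept the annotation's symbol, and no symbol changed. These entries include 6 control probe sets, which were left out. No gene was named from a probe set that lists several. No coordinates are given because the array files name no genome build.

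The deposited log2 values were used without further normalization. Probe sets with a mean over the 6 arrays of at least 4 were kept, which left 22408 probe sets (41.0%). A gene was represented by its kept single-gene probe set with the highest mean, which gave 10848 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups of 3 arrays, no covariate), two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. A gene took the adjusted p of its representative. Adjusted p values in the report come from this fit unless another test is named, and log2 fold changes are anti-miR-21 minus mock with the standard error of the fit. Group values are means of log2 expression with the SD over 3 arrays. The labels call the replicates biological without saying whether cultures were separate in time, so p values measure the spread between these samples. Precision is limited by the number of arrays.

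Before the data were examined, 18 gene lists were fixed, covering published miR-21 targets, signalling, cell cycle, stress, metabolic and matrix genes, and cell type markers. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 17 lists with more than 1 kept gene. An estimated correlation and fry, which tests whether a list's genes move one way on balance, were run beside it. Genes named in the text followed a rule fixed at the same time. It takes the 10 largest changes in each direction among called genes whose arrays do not overlap between groups, 8 genes chosen for their link to miR-21, and the 4 members of each list with the smallest p (2 for marker lists). Genes named outside this rule are marked. A planned test of miR-21 seed matches in 3' untranslated regions was not run because no transcript sequence was used here. Some of the 8 genes and 1 planned control transcript are not reported here.

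A further test, added after the data were seen, asked whether probe sets of 1 gene moved apart. Each kept probe set was expressed per array as its difference from the mean of the gene's other kept probe sets, these differences were tested with limma, and p values were combined per gene with Simes' method and adjusted over genes.

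The fits were tested on simulated data with the real means and the variances moderated by eBayes, drawn independently for each probe set. Over 22408 probe sets, limma recovered 83 of 100 changed by 1.5-fold and 100 of 100 changed by 2-fold, with 8 false calls. For the test of probe sets moving apart, over 5285 genes, 96 of 100 shifts of 1 log2 unit were recovered with 3 false calls. A shift of 0.2 log2 units in the 43 kept published targets was recovered by camera. Of the 16 other lists, 1 was also called. Among them only the TGF-β response list shares kept genes with the targets (4 genes). Which list was called was not recorded. The simulated genes were uncorrelated, so this cannot show how camera performs on correlated genes. The inter-gene correlation estimated for the real published targets was 0.112.

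Alternatives were no filter, a filter at a mean of 6, quantile normalization, centring each array on its median, eBayes with trend and robust settings, the replicate number as a block, leaving out each array in turn, and averaging a gene's probe sets.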

Results

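The study measured the transcriptome of SK-Hep1 cells, an established human line from a liver adenocarcinoma, 16 hours after transfection with 20 nM of anti-miR-21 or with mock treatment. Anti-miR-21 is an oligonucleotide directed against miR-21, a microRNA that represses messenger RNAs bearing its seed match. The mock samples received no oligonucleotide. Each group held 3 arrays. Between 22277 and 22591 probe sets per array had a log2 value of at least 4. Correlations across kept probe sets were 0.99625 to 0.99828 within groups and 0.99387 to 0.99729 between groups. The first principal component held 50.4% of the variance. On it the mock arrays lay between -19.95 and -7.25, anti-miR-21 replicates 2 and 3 at 20.11 and 19.63, and anti-miR-21 replicate 1 at 3.51.

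Ratios of control probe sets along the ACTB and GAPDH transcripts, a measure of RNA integrity, were close in both groups. The ACTB 3' minus 5' difference was 0.564 ± 0.069 (SD, n = 3) in mock and 0.595 ± 0.009 (SD, n = 3) in anti-miR-21 (two-sided exact permutation test, p = 0.70). For GAPDH it was -0.270 ± 0.011 and -0.271 ± 0.012 (exact permutation p = 1). The smallest p that 3 arrays against 3 allow is 0.1, which the BioC hybridisation spike reached with a difference of -0.070.

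The first question was which transcripts changed in cells given anti-miR-21. Of 10848 genes tested, 99 were higher and 132 lower with anti-miR-21. At the level of probe sets, 247 were higher and 239 lower among 22408. The median log2 fold change was 0.50 among higher genes and -0.49 among lower genes, 40 genes rose and 43 fell by at least 1.5-fold, and 13 rose and 6 fell by at least 2-fold. All 231 called genes had non-overlapping arrays, as did 25.5% of all genes tested, against 10% expected by chance. Leaving out mock replicate 2 reduced the count to 38 genes, anti-miR-21 replicate 3 to 41, anti-miR-21 replicate 2 to 44 and mock replicate 3 to 80, whereas 198 were called without mock replicate 1 and 226 without anti-miR-21 replicate 1. Of the 34 called genes named by the rule, 7 passed with each array left out in turn (ANKRD46, KLHL15, DENND5B, CCNH, EFCAB7, DENND5A and GALC).

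Among called genes, the transcripts that rose most included regulators of inflammatory signalling and stress. ANKRD46, an ankyrin repeat gene, rose 3.39-fold, from 8.50 ± 0.03 to 10.26 ± 0.02 (SD, n = 3, limma adjusted p = 8.4e-05). KLHL15, an adaptor of cullin 3 ubiquitin ligases, rose 2.14-fold from 8.91 ± 0.08 to 10.01 ± 0.02 (limma adjusted p = 0.00121). NFKBIZ, a nuclear regulator of NF-κB target genes, rose 2.24-fold (log2 fold change 1.16 ± 0.157 SE). GDF15, a stress-induced cytokine, and ATF3, a stress-induced transcription factor, each rose 2.09-fold, with log2 fold changes of 1.07 ± 0.127 and 1.06 ± 0.184 (SE). THRB, the thyroid hormone receptor beta, rose 2.11-fold, and CASTOR1, an arginine sensor upstream of mTORC1, rose 2.07-fold. The largest folds came from dim probe sets. The probe set annotated to GCNA went from 4.10 ± 0.12 to 6.47 ± 0.57 and that annotated to MIR146A, the locus of an NF-κB-induced microRNA, from 4.44 ± 0.16 to 6.48 ± 0.54 (SD, n = 3), with limma adjusted p of 0.0117 and 0.0163. The probe set measures a long transcript and not the mature microRNA.

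Among called genes, the transcripts that fell most had varied functions. CCNH, the cyclin partner of CDK7, fell 2.76-fold, from 12.08 ± 0.05 to 10.62 ± 0.09 (SD, n = 3, limma adjusted p = 0.000686). EFCAB7, a ciliary protein, fell 2.69-fold and the long noncoding RNA LINC01139 2.28-fold. SMG9, a component of nonsense-mediated decay, fell 2.06-fold, RNASEH2B, a subunit of ribonuclease H2, 2.03-fold, and ERAL1, a mitochondrial ribosome assembly factor, 2.02-fold. DENND5A, an exchange factor for Rab GTPases, fell 1.96-fold from 11.03 ± 0.07 to 10.06 ± 0.04 (limma adjusted p = 0.00164). KMO, kynurenine 3-monooxygenase, fell 1.92-fold, CD163L1, a scavenger receptor, 1.90-fold, and GALC, the lysosomal galactosylceramidase, 1.85-fold. A second probe set of RNASEH2B went the other way (log2 fold change 0.26, limma adjusted p = 0.119), and the gene's call was lost with both averaged (-0.38, adjusted p = 0.0705) and without the filter (0.0543). Without the filter the calls of KMO (0.0502) and ATF3 (0.102) were also lost.

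**Figure D1:**
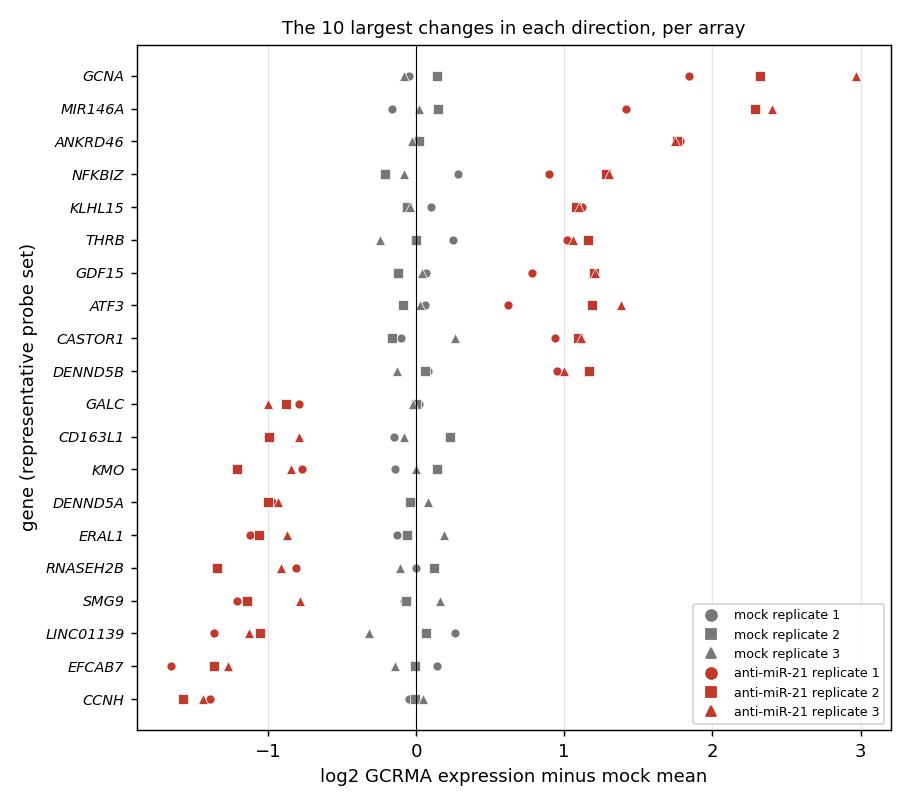
Log2 GCRMA expression minus the mock mean (x axis) in each of the 6 arrays for selected genes (y axis). Shown are the 10 genes whose representative probe set rose most and the 10 whose representative fell most. Both sets were taken only from called genes (limma adjusted p below 0.05) whose arrays do not overlap between groups. Grey symbols are mock arrays and red symbols anti-miR-21 arrays, with 1 symbol shape per replicate number. Replicate 1 of anti-miR-21 lies nearer to mock than the other anti-miR-21 arrays for GCNA, MIR146A, NFKBIZ, GDF15 and ATF3, whereas for ANKRD46 and KLHL15 the 3 arrays coincide.

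The next question was whether known targets of miR-21 moved. Of 58 genes fixed as targets, 43 were kept, 32 had a positive log2 fold change, 8 rose, none fell and 35 did not pass. With p values adjusted over the list alone, 16 rose and none fell. TIMP3, an inhibitor of metalloproteinases, rose 1.33-fold from 11.72 ± 0.05 to 12.13 ± 0.03 (SD, n = 3, limma adjusted p = 0.0149), and its 4 probe sets had log2 fold changes of 0.26 to 0.49. ZNF367, a zinc finger transcription factor, rose 1.72-fold, the deubiquitinase YOD1 1.63-fold and RMND5A, a subunit of the CTLH ubiquitin ligase, 1.29-fold. The other members that rose were TGFBR2, a TGF-β receptor, at 1.22-fold, and, named after their values were seen, GATAD2B, GID4 and TIAM1. The median of the list was 0.146 (camera, adjusted p = 2.15e-08). That call was lost with an estimated inter-gene correlation (adjusted p = 0.273). Per array, the list median was 0.105, 0.170 and 0.144 in the anti-miR-21 arrays and 0.075, -0.006 and -0.038 in mock. With fry the adjusted p was 0.0576 and the unadjusted p 0.00713. The number of members that rose was 0 without mock replicate 2, anti-miR-21 replicate 2 or anti-miR-21 replicate 3, 2 without mock replicate 3, 3 without anti-miR-21 replicate 1 and 6 without mock replicate 1. YOD1 was not called without the filter (adjusted p = 0.0699), nor TGFBR2 with median centring (0.0552), averaged probe sets (0.0546) or any 1 array left out.

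Among the genes fixed by name for their link to miR-21 and reported here, TIMP3 was the 1 called by its representative probe set. SPRY1, an inhibitor of growth factor signalling, had a log2 fold change of 0.47 ± 0.145 SE at a mock level of 4.31 (limma adjusted p = 0.161). RECK, a membrane inhibitor of metalloproteinases, had a representative probe set at 0.02 ± 0.047 SE (limma adjusted p = 0.865), whereas a dimmer probe set rose by 1.64 ± 0.232 SE, from 3.96 to 5.60 (limma adjusted p = 0.0228). The other 2 kept RECK probe sets had log2 fold changes of -0.05 and -0.08, and the representative is of a type that can cross-hybridise. VMP1, whose locus overlaps the miR-21 primary transcript, had a single-gene probe set with a log2 fold change of 1.36 ± 0.259 SE (limma adjusted p = 0.0536), with adjusted p values from 0.0287 to 0.188 over the alternatives. PDCD4 had 1 single-gene probe set, at 2.89 in mock and 2.94 in anti-miR-21, below the filter, so it was not tested. Probe sets that list several genes were not assigned to it, so this value does not show that PDCD4 was not expressed. The arrays do not measure mature miR-21, so its blockade could not be checked directly.

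NF-κB and cytokine genes shifted upwards. Of 28 fixed genes, 19 were kept, of which 7 rose, none fell and 12 did not pass. Adjusted over the list alone, 13 rose and none fell. The chemokines CXCL3, CXCL2 and CXCL1 rose 1.88-, 2.02- and 1.47-fold (limma adjusted p = 0.00936, 0.0184 and 0.019), and IL6, an inflammatory cytokine, rose 1.68-fold, from 9.95 ± 0.06 to 10.70 ± 0.19 (SD, n = 3, limma adjusted p = 0.0198). NFKBIZ was also a member, and the other 2, named after their values were seen, were the chemokine CXCL8 (1.81-fold) and the cytokine IL1A (1.79-fold). The CXCL chemokines are close paralogs, and the CXCL2 and CXCL8 probe sets, like those of GDF15 and ZNF367, are of a type that can cross-hybridise, so their separate values are uncertain. The list median was 0.389 (camera, adjusted p = 9.32e-14). That call was lost with an estimated correlation (adjusted p = 0.273), and the fry adjusted p was 0.0576. The number of members that rose was 0 without mock replicate 2, 1 without mock replicate 3 or anti-miR-21 replicate 2, 2 without anti-miR-21 replicate 3 and 4 without mock replicate 1. Per array, the list median lay at 0.275, 0.353 and 0.541 in the anti-miR-21 arrays and between -0.015 and 0.014 in mock.

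Among interferon response genes, of 24 kept genes, 3 fell and none rose, and the counts were the same adjusted over the list alone. IFIT1, an interferon-induced antiviral protein, fell 1.77-fold from 10.37 ± 0.10 to 9.55 ± 0.21, IFI44 fell 1.68-fold and SAMD9, an antiviral factor, 1.52-fold (limma adjusted p = 0.021, 0.0149 and 0.0163). IFIT3 had a log2 fold change of -0.22 (limma adjusted p = 0.143). The list as a whole did not pass (median -0.062, camera adjusted p = 0.124, fry adjusted p = 0.0576). None passed downward without mock replicate 2, anti-miR-21 replicate 2 or anti-miR-21 replicate 3, although the log2 fold changes of these 3 genes stayed negative. The call of SAMD9 was lost with probe sets averaged (adjusted p = 0.0842).

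The stress and immediate early lists shifted upwards with few single calls and unequal arrays. In the unfolded protein and integrated stress response list, 1 of 27 kept genes rose, ATF3, none fell, and 23 had a positive log2 fold change. Adjusted over the list alone, 3 rose. DDIT3, a pro-apoptotic stress factor, had a log2 fold change of 1.07 ± 0.224 SE (limma adjusted p = 0.0718), MTHFD2, a mitochondrial folate enzyme, 0.27 (adjusted p = 0.0985) and the transcription factor CEBPG 0.46 (adjusted p = 0.128). The list median was 0.230 (camera, adjusted p = 1.72e-05), a call lost with an estimated correlation (adjusted p = 0.477). Its median was -0.024 in anti-miR-21 replicate 1, within the mock range of -0.036 to 0.055, against 0.290 and 0.334 in replicates 2 and 3. Among immediate early and MAPK feedback genes, 1 of 25 kept genes rose, again ATF3, and none fell, with 8 rising when adjusted over the list alone. The transcription factors EGR1, KLF2 and FOSL2 had log2 fold changes of 0.54, 0.37 and 0.53 (limma adjusted p = 0.0652, 0.0824 and 0.102). HSPA5, an endoplasmic reticulum chaperone in the stress list, was named after its values were seen. A second probe set of it fell (log2 fold change -0.50, limma adjusted p = 0.0363), with its representative at 0.01. DDIT3 passed with the filter at 6, with probe sets averaged and without anti-miR-21 replicate 1 (adjusted p = 0.0475, 0.0462 and 0.00851). EGR1 passed with the filter at 6 (0.0428), with probe sets averaged (0.029) and without mock replicate 1. FOSL2 and CEBPG passed without anti-miR-21 replicate 1 (limma adjusted p = 0.0298 and 0.0465). The immediate early list's median was 0.173 (camera, adjusted p = 7.83e-07, and adjusted p = 0.477 with an estimated correlation), with 0.064 in anti-miR-21 replicate 1 and 0.221 and 0.233 in the others.

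**Figure D2:**
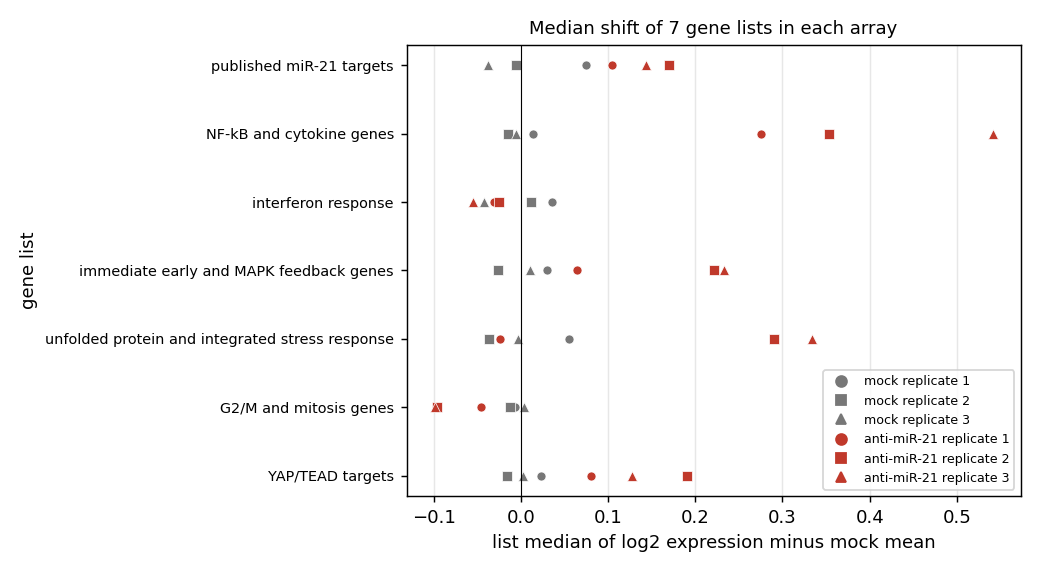
Median over the kept members of 7 gene lists of log2 expression minus the mock mean (x axis) in each array, 1 row per list. Grey symbols are mock arrays and red symbols anti-miR-21 arrays. Replicate 1 of anti-miR-21 stands at -0.024 for the unfolded protein and integrated stress response list, among the mock arrays, and at 0.275 for NF-κB and cytokine genes, above them.

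No representative probe set in the cell cycle lists was called. In the G2/M and mitosis list none of 36 kept genes passed on its representative, 6 had a positive log2 fold change, and 3 fell when adjusted over the list alone. The kinesin KIF2C, the phosphatase CDC25C, the cyclin CCNB1 and the topoisomerase TOP2A had log2 fold changes of -0.33, -0.43, -0.22 and -0.37 (limma adjusted p = 0.0569, 0.0698, 0.0858 and 0.133). The list median was -0.077 (camera, adjusted p = 0.00785, and adjusted p = 0.477 with an estimated correlation). A second probe set of CDC25C fell (log2 fold change -0.74, limma adjusted p = 0.018). The gene passed with the filter at 6 (0.0485), with probe sets averaged (0.0151) and without mock replicate 1. KIF2C passed with the filter at 6, the trend and robust setting, averaging and without anti-miR-21 replicate 1 (adjusted p = 0.0353 to 0.0462). CCNB1 passed with the trend and robust setting (0.033). Without mock replicate 1 the camera adjusted p was 0.181. In the G1/S and DNA replication list none of 35 passed, and 1 fell adjusted over the list alone (median -0.041, camera adjusted p = 0.371). The replication factors GINS1 and MCM6 had log2 fold changes of -0.27 and -0.19, and the cyclins CCNE1 and CCNE2 of -0.32 and 0.38 (limma adjusted p = 0.0528, 0.139, 0.0843 and 0.140). GINS1 passed under 4 alternatives (adjusted p = 0.0239 to 0.0497) and CCNE2 with probe sets averaged (0.0389). None of 24 kept p53 targets passed, also when adjusted over the list alone (median 0.019, camera adjusted p = 0.371), with GADD45A, a growth arrest gene, at 0.42 and PMAIP1, a pro-apoptotic BH3 protein, at 0.46 (limma adjusted p = 0.0845 and 0.0993). Both passed without anti-miR-21 replicate 1 (limma adjusted p = 0.0374 and 0.0276).

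YAP/TEAD targets shifted upwards, with 1 of 23 kept genes rising, PTPN14, a phosphatase that binds YAP, by 1.25-fold (limma adjusted p = 0.0318), and none falling. That call was lost with any 1 array left out and with probe sets averaged (adjusted p = 0.111). Adjusted over the list alone, 2 rose. The kinase gene LATS2 and the matricellular gene CCN2 had log2 fold changes of 0.39 and 0.27 (limma adjusted p = 0.0926 and 0.140). The list median was 0.133 (camera, adjusted p = 5.65e-05, and adjusted p = 0.273 with an estimated correlation). Of 20 TGF-β response genes, TGFBR2 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.143), and this list shares 4 kept genes with the published targets. Of 25 glycolysis and hypoxia genes, BNIP3, a mitophagy receptor, fell 1.24-fold (limma adjusted p = 0.0457) and none rose, with 5 falling adjusted over the list alone (camera adjusted p = 0.056). The call of BNIP3 was lost with any 1 array left out, without the filter (adjusted p = 0.0502), with median centring (0.0513) and with probe sets averaged (0.0561). The neuronal enolase ENO2 in that list had a log2 fold change of -0.37 (limma adjusted p = 0.0932, and 0.0381 without mock replicate 1).

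In 3 further lists no member passed on its representative probe set. Adjusted over the list alone, 1 gene rose and 1 fell in the microRNA machinery and none in the others. Of 19 cholesterol and fatty acid synthesis genes, HMGCS1, an enzyme of the mevalonate pathway, had a log2 fold change of -0.26 and the sterol carrier STARD4 0.29 (limma adjusted p = 0.136 and 0.113, list camera adjusted p = 0.0891). Of 32 extracellular matrix and mesenchymal genes, COL4A1, a basement membrane collagen, had 0.50 and LOX, a collagen crosslinking enzyme, -0.23 (limma adjusted p = 0.0821 and 0.131, list camera adjusted p = 0.387). Both passed with probe sets averaged (adjusted p = 0.0212 and 0.0198), and 2 other probe sets of LOX fell (log2 fold change -0.42 and -0.35, limma adjusted p = 0.0233 and 0.0258). Of 14 genes of the microRNA machinery, AGO4, an Argonaute, had 0.50, and the processing enzymes DROSHA and DICER1 had -0.21 and 0.25 (limma adjusted p = 0.0895, 0.0976 and 0.143, list camera adjusted p = 0.613). DICER1 passed without mock replicate 1 (limma adjusted p = 0.0454).

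Cell type markers were mostly below the filter, and none passed on its representative probe set. Of 22 hepatocyte markers 3 were kept, among them SERPINA1 at 11.87 ± 0.05 in mock and 11.97 ± 0.02 in anti-miR-21, and AFP at 4.28 and 4.16. Of 20 endothelial markers 5 were kept, with ROBO4 at a log2 fold change of 0.48 and EGFL7 at -0.19 (limma adjusted p = 0.131 and 0.247), and 1 passed adjusted over the list alone. ROBO4 passed without mock replicate 3 (limma adjusted p = 0.0422). Of 14 fibroblast and smooth muscle markers 6 were kept, with RGS5 at 0.35 and TAGLN at 0.06 (limma adjusted p = 0.166 and 0.553, and 0.0499 for RGS5 with probe sets averaged). Of 18 immune cell markers only CD14 was kept, at 5.24 ± 0.02 and 5.36 ± 0.19 (SD, n = 3, limma adjusted p = 0.574). The camera adjusted p values of the 3 lists with more than 1 kept gene were 0.613 for hepatocyte, 0.302 for endothelial, and 0.613 for fibroblast and smooth muscle markers. The fibroblast and smooth muscle list had a median of -0.027 but a mean of 0.022 and an upward test, and the hepatocyte list a median of 0.017 but a mean of -0.001. Adjusted over the list alone, no hepatocyte, fibroblast and smooth muscle, or immune cell marker passed.

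**Figure D3:**
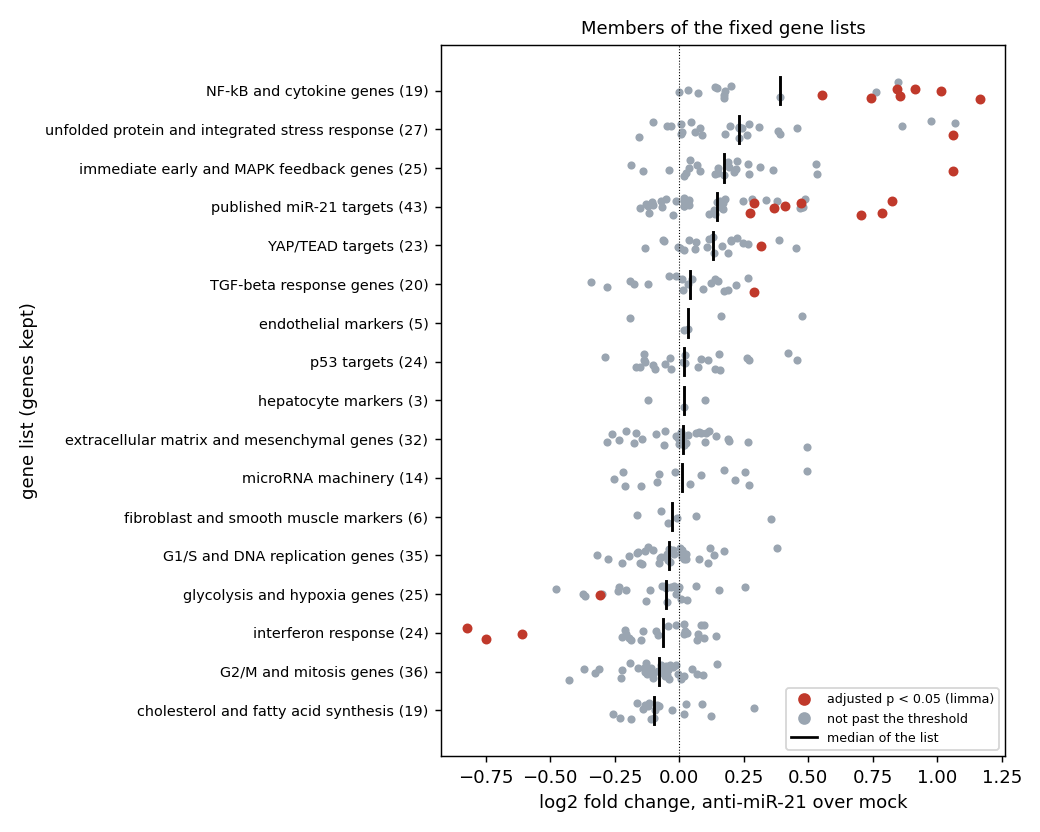
Log2 fold change of anti-miR-21 over mock (x axis) for each kept member of the 17 lists with more than 1 kept gene (y axis, kept genes in parentheses). Red points passed limma adjusted p below 0.05, grey points did not, and black bars are list medians, which run from -0.096 for cholesterol and fatty acid synthesis to 0.389 for NF-κB and cytokine genes.

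Different probe sets of the same gene did not always move together. Among 54 genes with more than 1 called single-gene probe set, 10 had probe sets called in opposite directions. DENND5B, an exchange factor for Rab GTPases, had its representative probe set 238917_s_at at a log2 fold change of 1.04, 243613_at at 0.93 and 228551_at at -1.45 (limma adjusted p = 0.00424, 0.0166 and 0.000728). Its other kept probe set, 215058_at, was at -1.205 (limma adjusted p = 0.0841). The following genes were named after their values were seen. MRS2, a mitochondrial magnesium channel, had 228542_at at 1.28 and 218536_at at -0.87 (limma adjusted p = 0.00363 and 0.00304). Its representative 218538_s_at was at -0.54 and the dim 224101_x_at at 0.17 (limma adjusted p = 0.0184 and 0.684). RPP30, a subunit of ribonuclease P, had 1556063_s_at at 1.16, 1556061_at at -1.14 and 1556062_at at -0.60. Its probe set 203436_at was at 0.00 (log2 fold change -0.002, limma adjusted p = 0.989). ZNF655, a zinc finger gene, had 223302_s_at at -1.24, 225945_at at 0.36 and 1554726_at at 0.49 (limma adjusted p = 0.000728, 0.0268 and 0.0718). In a direct test of the difference between probe sets, 75 of 5285 genes passed (limma on within-gene differences, Simes p, Benjamini-Hochberg adjustment), among them 9 of the 10. In the fixed lists, 9 genes not called on their representative had another probe set called, higher for PLEKHA1, RECK, ICAM1, KLF6 and THBS1 and lower for CDC25C, MAD2L1, HSPA5 and LOX. The number of genes moved apart was 27 without anti-miR-21 replicate 3, 28 without mock replicate 2, 35 without mock replicate 3 and 37 without anti-miR-21 replicate 2, and 104 without anti-miR-21 replicate 1.

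**Figure D4:**
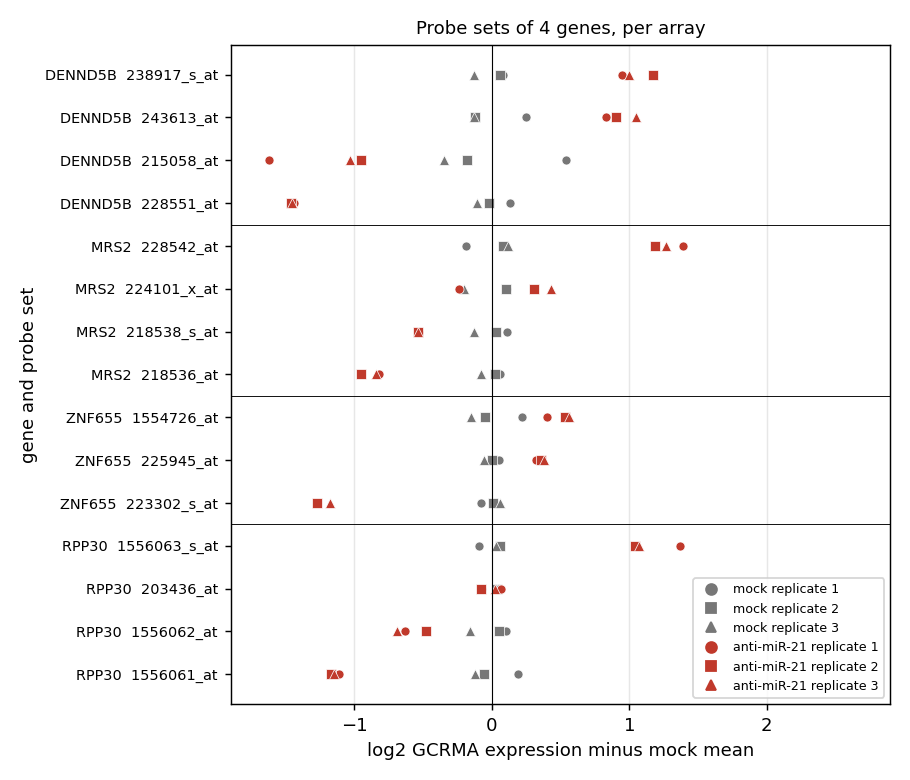
Log2 GCRMA expression minus the mock mean (x axis) in each array for every kept single-gene probe set of RPP30, ZNF655, MRS2 and DENND5B (y axis). Grey symbols are mock arrays and red symbols anti-miR-21 arrays, and within each gene 1 or more probe sets lie below 0 and others above 0 in all 3 anti-miR-21 arrays.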

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

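The limma test of all kept probe sets was planned, and the probe sets named here were singled out after it was seen. Across all kept probe sets, 486 of 22408 passed the threshold in limma. Probe sets that list no gene enter no gene comparison. Of the 1766 of these that were kept, 29 passed, a smaller share, with 17 higher and 12 lower. Probe set 230571_at had the largest log2 fold change among them, 3.94 ± 0.163 SE, from 4.13 ± 0.34 in mock to 8.07 ± 0.09 with anti-miR-21 (SD, n = 3, limma adjusted p = 0.000608). Probe set 239863_at rose by 1.81 from a dim 3.59 (limma adjusted p = 0.0112). Probe sets 233506_at and 238842_at had log2 fold changes of -0.77 and -0.77 (limma adjusted p = 0.00433 and 0.00923). The mock levels of 230571_at and 239863_at lie near the GCRMA floor, so the size of their folds is uncertain. Each is a signal in data outside the gene comparisons, above or below the mock arrays without overlap. Their genes were not named here, and no biological explanation was tested.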

How the results depend on the processing

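The test of probe sets moving apart, with its alternatives, was chosen after the data were seen. Over 440 alternatives of the 34 called genes named by the rule, 308 kept the call, 131 lost it and 1 reversed. No called named gene changed direction under any alternative except DENND5B, whose log2 fold change was -0.17 with probe sets averaged (averaging probe sets of opposite sign, by construction). The replicate numbers did not pair the arrays, whose deviations from the group means correlated at -0.361, -0.266 and -0.002 for numbers 1, 2 and 3. With the replicate block, which leaves fewer residual degrees of freedom, 91 probe sets passed (54 higher, 37 lower) and 32 genes (16 higher, 16 lower, all by at least 1.5-fold), 30 of them among the 231, and 0 published targets and 0 NF-κB genes rose. In the other group, 1 of the 6 arrays correlated best with the array of its own number. Without the filter, with more probe sets tested, 158 probe sets were higher, 26 genes rose by at least 1.5-fold and 5 published targets rose. In that setting the G1/S, cholesterol, and glycolysis and hypoxia lists passed downward (camera adjusted p = 0.00934, 0.000143 and 0.000465), and the microRNA machinery and matrix lists turned downward without passing (0.849 and 0.933). With probe sets averaged, 355 genes passed (161 higher), of which 176 were among the 231, 6 of the 231 changed sign, and glycolysis and hypoxia passed (0.0187). The cause was not tested. With an estimated correlation no list passed. The published targets, NF-κB and YAP/TEAD lists had adjusted p = 0.273 and the immediate early, G2/M and stress lists 0.477. With fry the values were 0.0576 for the former 3, 0.0887 for immediate early and G2/M and 0.234 for stress, and microRNA machinery turned downward (0.863). Lists that camera did not call had equal fry values, 0.0576 for interferon response and 0.0887 for cholesterol and for glycolysis and hypoxia. The lowest correlation within a group was 0.99898 without the filter and 0.99482 with the filter at 6. Quantile normalization, median centring, the trend and robust setting and the filter at 6 left the counts of probe sets, genes and list members within 1.5 times and changed no list's call.

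Leaving out 1 array gave 96 to 572 probe sets (47 to 345 higher, 47 to 227 lower) and 38 to 226 genes (14 to 91 higher, 24 to 135 lower, 12 to 52 and 20 to 48 by at least 1.5-fold). Each of these 8 counts was highest without anti-miR-21 replicate 1. Published targets that rose numbered 0 to 6, NF-κB genes that rose 0 to 8 and interferon genes that fell 0 to 3. The G2/M list ranged from 0.00144 to 0.181, cholesterol from 0.0286 to 0.262, glycolysis and hypoxia from 0.00685 to 0.175, and matrix genes from 0.0588 to 0.763, turning downward without mock replicate 2 (0.668). Genes whose probe sets moved apart numbered 27 to 104, 50 without probe sets of the _s_at, _x_at and _a_at types, and 77 with the filter at 6. The seed match test was not run. Signal near the GCRMA floor limits the folds of GCNA, MIR146A, the dim RECK probe set and probe sets 230571_at and 239863_at.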

Other observations

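In this part the limma calls and the tests of fixed lists were planned, while the tests of other lysosomal and fatty acid genes, of anti-miR-21 replicate 1, of interferon genes that fell and of probe sets moving apart were chosen after the results were seen. Lysosomal and fatty acid genes outside the fixed lists were among those that fell. The lysosomal genes GALC, NEU1, LMBRD1 and ARSK had log2 fold changes of -0.89, -0.56, -0.66 and -0.47, and the fatty acid genes CROT, SLC25A20, HACL1 and BDH2 had -0.66, -0.48, -0.68 and -0.48, each past the limma threshold. CROT was among the genes whose probe sets moved apart, its second probe set having a log2 fold change of 0.40 (limma adjusted p = 0.233). The hypothesis that either group fell as a whole was tested on lists without these 8 genes. Neither passed, with camera adjusted p = 0.262 for 30 other lysosomal genes (median -0.037) and 0.392 for 26 other fatty acid oxidation genes (median -0.037), so the fall was not shown beyond the genes named.

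The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 486 probe sets and 231 genes, and the highest of the other 9 gave 0 for both, so 1 of the 10 reached the real value. Each of the other splits has arrays of both groups on each side, so the group difference adds to its residual spread. Its count of 0 is therefore no estimate of the calls expected by chance. For lists at the preset correlation, the real split gave 6 and the highest other 7, and 4 of the 10 splits gave at least 6. The preset camera p of the published targets was below 0.05 in 5 of the other 9 splits, the smallest being 2.24e-05 against 2.53e-09 in the real split. The 3 splits with 7 lists each set anti-miR-21 replicate 1 apart from replicates 2 and 3. These splits also keep part of the contrast between the groups, so their lists cannot tell other structure among the arrays from the group difference itself.

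The position of anti-miR-21 replicate 1 was weighed further. Over the 572 probe sets called without it, anti-miR-21 replicate 1 showed a median of 0.661 of the shift of replicates 2 and 3. Treated alike, replicates 2 and 3 showed 0.980 and 0.996, over the 106 and 96 probe sets called without each. Those probe sets were called with replicate 1 included, so the 3 medians rest on different probe sets and part of the gap may come from that selection. An exchange with a mock array is argued against by the value of 0.661, since each mock array in turn also kept a median of at least 0.819 of its own group's shift. A uniformly weaker response in replicate 1 stays open. As regression slopes, the stress response list kept 0.092 of the shift, the called probe sets 0.586 and the published miR-21 targets 0.953 (by list medians, 0.105 against 0.163), but the stress list was singled out for this departure, and its 95% bootstrap interval over genes, -0.143 to 0.321, became -0.801 to 0.962 when widened for its estimated inter-gene correlation of 0.517.

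The rise of NF-κB and cytokine genes, with a list median of 0.389, may follow from miR-21 blockade or from transfection of an oligonucleotide of any sequence. These cannot be told apart because mock cells received no oligonucleotide. The same limit holds for every other difference between the groups reported here. Sensing through an interferon response stays open too. Of 24 interferon response genes none rose and 3 fell, against 1.19% of other genes (one-sided Fisher's exact test, p = 0.00296), but that test was chosen on the count it restates and treats co-regulated genes as independent. None passed downward without mock replicate 2, anti-miR-21 replicate 2 or anti-miR-21 replicate 3. The log2 fold changes of the 3 stayed negative with each array left out. They ran from -0.943 to -0.745 for IFIT1, -0.806 to -0.672 for IFI44 and -0.676 to -0.549 for SAMD9, so the calls were lost and the direction was not.

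The 75 genes whose probe sets moved apart were counted in the real split, which was 1 of 10, and the highest count among the other 9 was 0. Those splits mix the groups on each side, so this 0 is no estimate of chance either. With plain probe sets alone 2.23% of testable genes passed (50 of 2240), compared with 1.42% with all types (75 of 5285). The _s_at, _x_at and _a_at types therefore do not account for every call. Cross-hybridisation itself stays open, since the rates rest on different genes and the type of a probe set does not settle it. The only rising probe set of RPP30 and the only falling one of ZNF655 were of the _s_at type. Dim probe sets are argued against, since 1.74% passed with a mean of at least 6. Probe sets annotated to the wrong gene stay open for all 75, because no probe position was used.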
